A study of Mus musculus with 12 samples.

How the data were processed

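RNA was read in 12 libraries, 3 for each of 4 groups: Vehicle, TGFB1, Tgfbr2KO_Vehicle and Tgfbr2KO_TGFB1. Per the labels' protocols, RNA was isolated with a column kit and libraries were made from polyadenylated RNA by a sequencing provider. The authors deposited 1 table of FPKM values per gene symbol, with 25203 genes of which 4702 were 0 in every library. Per the submitters' processing notes, kallisto 0.46.1 and DESeq2 1.40.1 were used and the genome build was mm9. How these tools led to the FPKM table, and how libraries were scaled to each other, is not stated, and read counts were not used here, so tests were run on log-scaled FPKM. The annotation at hand was of another build, so no coordinates are given. Each column of the table was matched to a library by its group and by the number that the labels give for it.

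The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. FPKM values were taken as log2(FPKM + 1), a scale that understates the change of genes with low FPKM, and folds are ratios of group mean FPKM. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested (12641). Group means were fitted with limma to all 12 libraries (8 residual degrees of freedom), with empirical Bayes moderation and a variance trend. P-values were adjusted over all tested genes by Benjamini and Hochberg with a threshold of 0.05. The comparisons were TGFB1 minus Vehicle, Tgfbr2KO_TGFB1 minus Tgfbr2KO_Vehicle, the interaction (the second change minus the first) and Tgfbr2KO_Vehicle minus Vehicle. The labels do not say that the 3 libraries of a group come from separate animals, so p-values measure the spread between libraries.

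Gene lists for 20 pathways and 8 cell types were fixed, with the comparisons and their tests, before the data were examined. Of these, 24 had at least 5 tested members and were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists within each comparison. The 4 others had too few tested members: epithelial 2, enteric glia and neuron 2, mesothelial 0 and interstitial cell of Cajal 3. Members were also adjusted over the list alone. The genes named are, for each comparison, the 12 largest rises and 12 largest falls past the threshold with a mean of at least 5 FPKM in a compared group and no overlap between the groups (for the interaction, without the overlap condition and with the mean in any group), up to 4 called members of each list, and genes fixed beforehand. Those were Tgfbr2, Tgfb1, Pdgfra, Smad7, Acta2, Ccn2, Col1a1, Grem1, Rspo3, Bmp4 and Il6, and 1 more that is not reported here. Marker genes of other cell types are given as levels.

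The labels give each group the replicates 1, 2 and 3, and in all 4 groups their descriptions carry 31, 121 and 123 in that order. Deviations of same-numbered libraries from their group means correlated across genes within both genotypes, at 0.391, 0.445 and 0.408 between Vehicle and TGFB1 and at 0.588, 0.227 and 0.529 between Tgfbr2KO_Vehicle and Tgfbr2KO_TGFB1. Between Vehicle and Tgfbr2KO_Vehicle the correlations were 0.336, -0.0867 and 0.412. In all 4 groups 34 genes, among them near-identical gene copies, separated the 3 numbers. The labels thus share the numbers over the groups, while the correlations come from the data. Values with the number as a block are given beside those without where a call changed or a count of calls moved by over 1.5 times. The labels do not say what a number stands for.

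Relative depth was estimated from nonzero genes below 0.5 FPKM in both a library and Vehicle replicate 1. The most frequent ratio of their FPKM to that in Vehicle replicate 1 was inverted to give the depth, with Vehicle replicate 1 as 1. It was 1.05 and 0.962 for Vehicle replicates 2 and 3, and 0.799, 0.744 and 0.794 for TGFB1. For Tgfbr2KO_Vehicle it was 0.886, 0.859 and 1.02, and for Tgfbr2KO_TGFB1 0.803, 1.24 and 0.835. Absolute depth is not known. The median standard error of a log2 change between 2 groups was 0.109, and its 95% interval reached 0.242 to either side. The scripts were tested on simulated data with 200 changed genes among 12641 and independent noise of the same spread in all groups. In the TGFB1 comparison they recovered 41.8% of genes changed by a log2 of 0.5, 86.6% at 1 and 90.9% at 2, with 6 false calls. For the interaction this was 32.8%, 73.1% and 93.9% with 5 false calls, and for the vehicle comparison 46.3%, 82.1% and 98.5% with 11.

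Because 2 comparisons share the Vehicle libraries, their correlation and overlap are set beside 100 simulations of unchanged groups. A second set, chosen after seeing the data, let libraries of 1 number deviate together at the correlations of the residuals (0.302 for Vehicle and TGFB1, 0.193 for Vehicle and Tgfbr2KO_Vehicle, and 0.211 for TGFB1 and Tgfbr2KO_Vehicle). The alternatives tried were the replicate block, pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, upper-quartile scaling, quantile normalization, median centring, no variance trend, library weights, a fit to the compared libraries alone and leaving out each library. A block within each genotype, leaving out all 4 libraries of a number, and leaving out single libraries in the list tests and relations were chosen after seeing the data. Each group was also split in other ways against its partner, with 10 splits of 6 libraries and 100 drawn reassignments for the interaction. No library was left out of the tests.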

Results

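The expression of genes was measured in 12 RNA-seq libraries from primary cultures of mouse intestinal stromal fibroblasts that carry low Pdgfra reporter signal. Pdgfra encodes a platelet-derived growth factor receptor that marks stromal fibroblasts. The cultures formed 4 groups of 3 libraries. Cultures not labelled knockout received vehicle (Vehicle) or recombinant TGFB1, the ligand of the TGF-beta receptors (TGFB1). Cultures labelled Tgfbr2KO, for the type 2 TGF-beta receptor gene, received the same vehicle (Tgfbr2KO_Vehicle) or TGFB1 (Tgfbr2KO_TGFB1). The design asks what added TGFB1 does to these cells, and the Tgfbr2KO cultures measure how much of the response remains without the canonical receptor. Values are FPKM per gene symbol as deposited, and 12641 genes with at least 1 FPKM in at least 3 libraries were tested. A library's FPKM summed to between 498669 and 569510. The number of reads per library was not given in the sources used here, but low values placed the TGFB1 libraries at a relative depth of 0.779 ± 0.0304 (SD, n = 3), against 1.00 ± 0.0423 (SD, n = 3) for Vehicle. In the Tgfbr2KO libraries it was 0.921 ± 0.0855 (SD, n = 3) with vehicle and 0.961 ± 0.246 (SD, n = 3) with TGFB1.

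Tgfbr2 itself was read in every library. Its FPKM was 48.0, 38.2 and 78.8 in Vehicle replicates 1, 2 and 3, and 56.5, 70.6 and 74.6 in TGFB1 replicates 1, 2 and 3. In Tgfbr2KO_Vehicle it was 27.0, 35.2 and 41.9, and in Tgfbr2KO_TGFB1 it was 31.6, 38.0 and 62.4. Tgfbr2 was lower in each Tgfbr2KO library than in both other libraries of its number. The labels do not give the deleted part of the gene, and a whole-gene FPKM cannot check a deletion that leaves most of the transcript. The vehicle comparison of Tgfbr2 gave a log2 change of -0.61 (SE 0.30, limma adjusted p = 0.260), and an adjusted p of 0.0450 with the replicate number as a block.

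The first principal component held 46.9% of the variance and set the TGFB1 libraries apart from the other 9. TGFB1 libraries had scores from 49.0 to 50.3, and no other library scored above -8.65. The second component held 21.8% and spread libraries of one group by replicate number, with Vehicle replicate 3 at 38.6 and Tgfbr2KO_Vehicle replicate 1 at -34.4. Fibroblast transcripts were abundant in every group: the mean over the 12 fibroblast markers was 767 ± 221 FPKM in Vehicle, 1107 ± 54.3 in TGFB1, 423 ± 72.3 in Tgfbr2KO_Vehicle and 568 ± 201 in Tgfbr2KO_TGFB1 (SD, n = 3). Some macrophage RNA was present: Lyz2, a lysozyme of macrophages, ranged from 24.8 to 547 FPKM among Vehicle libraries and from 8.28 to 250.1 FPKM among TGFB1 libraries. Mean values over the epithelial, endothelial and mesothelial markers stayed below 5 FPKM in every library, while Krt8, a keratin of simple epithelia, reached 25.8 FPKM in Tgfbr2KO_Vehicle replicate 1. Other marker lists were higher, with library means of 132 to 280 FPKM for smooth muscle and pericyte and 17.8 to 28.8 FPKM for enteric glia and neuron. Only 2 of the 10 enteric glia and neuron markers reached 1 FPKM in at least 3 libraries, so that mean rests on few genes.

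**Figure D1:**
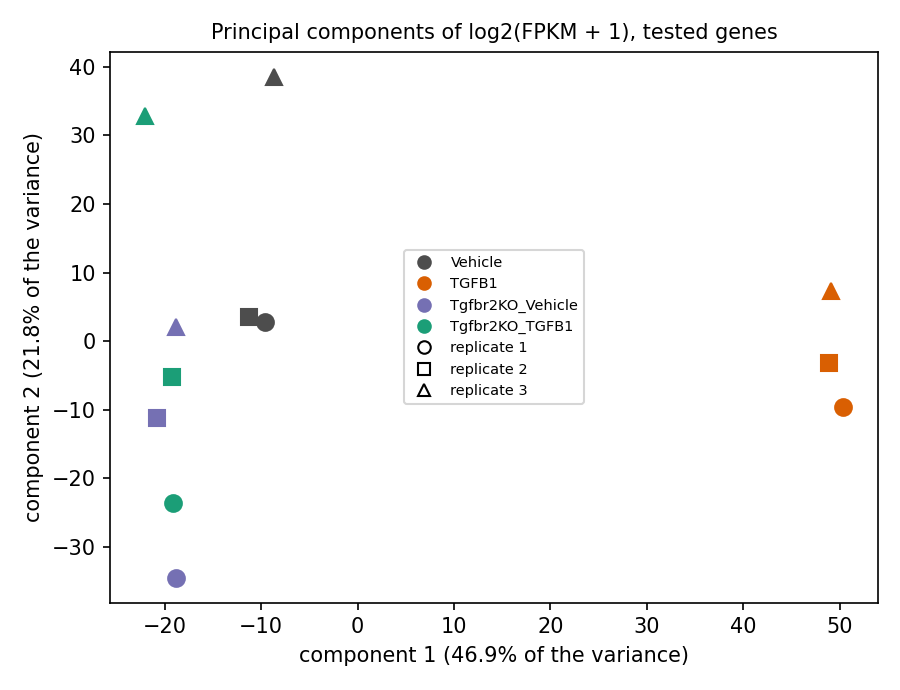
Scores of the 12 libraries on the first 2 principal components of log2(FPKM + 1) over the tested genes, coloured by group and shaped by replicate number. Component 1 (46.9% of the variance) separates the 3 TGFB1 libraries, which score from 49.0 to 50.3, from the other 9, and component 2 (21.8%) spreads libraries within a group.

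TGFB1 was first compared with vehicle in cultures not labelled knockout. Of the 15 tested genes for stem cell niche factors and WNT agonists, 10 fell and 2 rose (10 down and 3 up adjusted over the list alone). Grem1, a BMP antagonist of the crypt base, fell from 723 ± 74.8 to 274 ± 56.3 FPKM (SD, n = 3), a log2 change of -1.41 (SE 0.15, limma adjusted p = 8.51e-05). Rspo3, an R-spondin that amplifies WNT signals, fell from 11.5 ± 5.22 to 0.941 ± 0.310 FPKM (log2 -2.62, SE 0.40, adjusted p = 0.000836). Fgf10, a growth factor for epithelium, fell 20.1-fold in mean FPKM, Cd34 15.9-fold and Rspo1 62.5-fold (log2 -3.81, -3.81 and -2.88). The ratio for Rspo1 rests on a low mean with TGFB1. Pdgfra fell from 142 ± 20.7 to 15.2 ± 4.01 FPKM, which is 9.37-fold lower (log2 -3.16, SE 0.38, adjusted p = 0.000197). The list as a whole moved down relative to other genes (limma camera, median log2 -1.56, adjusted p = 6.54e-05), also with an estimated correlation (adjusted p = 0.0278).

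Bmp4, a ligand that promotes epithelial differentiation, was 12.5-fold lower with TGFB1 in the same cultures (15.5 ± 4.26 against 1.24 ± 0.343 FPKM, log2 -2.86, SE 0.23, adjusted p = 1.99e-05). Of 12 tested BMP-SMAD targets 9 fell and none rose, over all genes and adjusted over the list alone, among them Id2 (log2 -2.34), Id1 (-1.60), Atoh8 (-1.57) and Id4 (-1.30). That list passed the camera test (adjusted p = 1.48e-05), but not with an estimated correlation (adjusted p = 0.101). The list of BMP ligands and telocyte markers split, with 5 members lower and 3 higher of 12 (the same counts adjusted over the list alone), and did not pass (camera adjusted p = 0.409).

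Acute phase and inflammatory transcripts were among the deepest falls. Saa3, an acute phase apolipoprotein, fell from 2602 ± 281 to 8.94 ± 2.85 FPKM (SD, n = 3), or 291-fold (log2 -8.07, SE 0.56, limma adjusted p = 8.54e-06). Lcn2, which encodes an iron-sequestering lipocalin, fell from 100.4 ± 28.4 FPKM by a log2 change of -6.35. Its 464-fold ratio of means rests on a low mean with TGFB1. The neutrophil chemokine gene Cxcl5 fell 47.9-fold from 667 ± 110.2 FPKM. Complement C3 fell 9.84-fold, and the cytokine gene Il6 fell from 65.7 ± 6.31 to 14.0 ± 4.41 FPKM (log2 -2.20, SE 0.20, adjusted p = 3.82e-05). In all, 12 of 24 tested inflammatory fibroblast genes fell and 1 rose (15 and 2 adjusted over the list alone). Leukocyte markers did not move alike: S100a8, a calprotectin gene of neutrophils, was at 0.727 to 11.2 FPKM in Vehicle and 0 to 0.967 FPKM in TGFB1, and Lyz2 at 372, 24.8 and 547 FPKM in Vehicle replicates 1, 2 and 3 and 214, 8.28 and 250.1 FPKM in TGFB1, while Csf1r was higher with TGFB1 in replicates 1 and 3 (means of 5.15 FPKM in Vehicle and 5.59 FPKM in TGFB1). None of the 3 passed the threshold (for S100a8 adjusted p = 0.201, or 0.0375 with the replicate block). Camera did not call the leukocyte list (adjusted p = 0.409), but 1 of its 12 tested members passed, Cd14, which fell (log2 -1.04, limma adjusted p = 0.0325). Cd68 did not pass, but it was lower with TGFB1 in all 3 replicates (means of 10.1 FPKM in Vehicle and 3.84 FPKM in TGFB1). The inflammatory fibroblast list's median log2 change was -0.92 (camera adjusted p = 3.51e-06), and its adjusted p was 0.0747 with an estimated correlation. Other genes with the largest falls were Ptn, Ptx3, Lgi2, Spon2, Igfbp5, Prelp, Igfbp4, Vegfd and Mgp, with log2 changes from -5.63 to -3.87. Ptn and Mgp varied widely among Vehicle libraries, at 253 ± 200.3 and 50.2 ± 38.1 FPKM.

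Of 25 fibrillar collagen and matrix genes 17 rose and 2 fell (18 and 2 adjusted over the list alone). Eln, the gene of elastin, rose from 4.83 ± 5.22 to 133 ± 21.5 FPKM (log2 4.87, SE 0.64, limma adjusted p = 0.000341), Col5a3 rose 9.58-fold to 119 ± 15.2 FPKM, and fibronectin (Fn1) rose 2.86-fold from an already high 1518 ± 291 FPKM. Col1a1, the chain of the main fibrillar collagen, was at 2864 ± 901 FPKM with vehicle and 4046 ± 282 with TGFB1 and did not pass (log2 0.54, SE 0.30, adjusted p = 0.197). Not every collagen was higher: Col3a1 was at 635, 610 and 1738 FPKM in Vehicle replicates 1, 2 and 3. In TGFB1 replicates 1, 2 and 3 it was at 350, 430 and 501 FPKM. Of 20 early TGFB-SMAD targets 13 rose and none fell (16 up and 1 down adjusted over the list alone), led by the cell cycle inhibitor gene Cdkn2b (log2 2.54), Bhlhe40 (1.86), the NADPH oxidase gene Nox4 (1.80) and Spsb1 (1.68). Ccn2, a matricellular protein gene, rose 2.98-fold (log2 1.61, SE 0.34, adjusted p = 0.00559). The inhibitory SMAD gene Smad7 had a log2 change of 0.80 (SE 0.30) that missed the threshold (adjusted p = 0.0648), as did that of smooth muscle actin, Acta2 (0.37, SE 0.14, 0.0739). With the replicate number as a block both passed, with adjusted p of 0.00287 and 0.0174.

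Contractile and actin genes rose in 11 of 20 cases with none lower (13 adjusted over the list alone), by smaller steps: Itga5 rose by a log2 change of 1.25, Tpm1 by 0.89, Tagln by 0.82 and Smtn by 0.71. The early TGFB-SMAD targets passed the camera test with the preset correlation (median log2 0.88, adjusted p = 5.23e-07) and with an estimated correlation (adjusted p = 0.00797). The matrix list (adjusted p = 6.54e-05) and the contractile list (adjusted p = 6.53e-05) did not pass with an estimated correlation (adjusted p = 0.342 and 0.503). Among secreted signals, the growth factor list rose in 11 of 19 members and fell in 3 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0198, or 0.101 as adjusted p with an estimated correlation). Hbegf, an EGF receptor ligand gene, rose 7.82-fold to 129 ± 11.8 FPKM, and Fgf21 rose from 0.0610 ± 0.0599 to 6.42 ± 2.02 FPKM. Igfbp5 and the KIT ligand gene Kitl fell, by log2 changes of -4.09 and -2.61. The Notch ligand gene Jag1 rose 10.4-fold to 94.6 ± 5.58 FPKM (SD, n = 3), and Odaph, Tfpi2, Mmp9, Olfm2, Stmn4 and Ctsw were among the other genes with the largest rises, at log2 changes from 2.96 to 4.97. Among pathway components Tgfb1 rose 1.83-fold and Tgfb2 3.23-fold, while Tgfbr3, the gene of betaglycan, fell 8.84-fold.

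**Figure D2:**
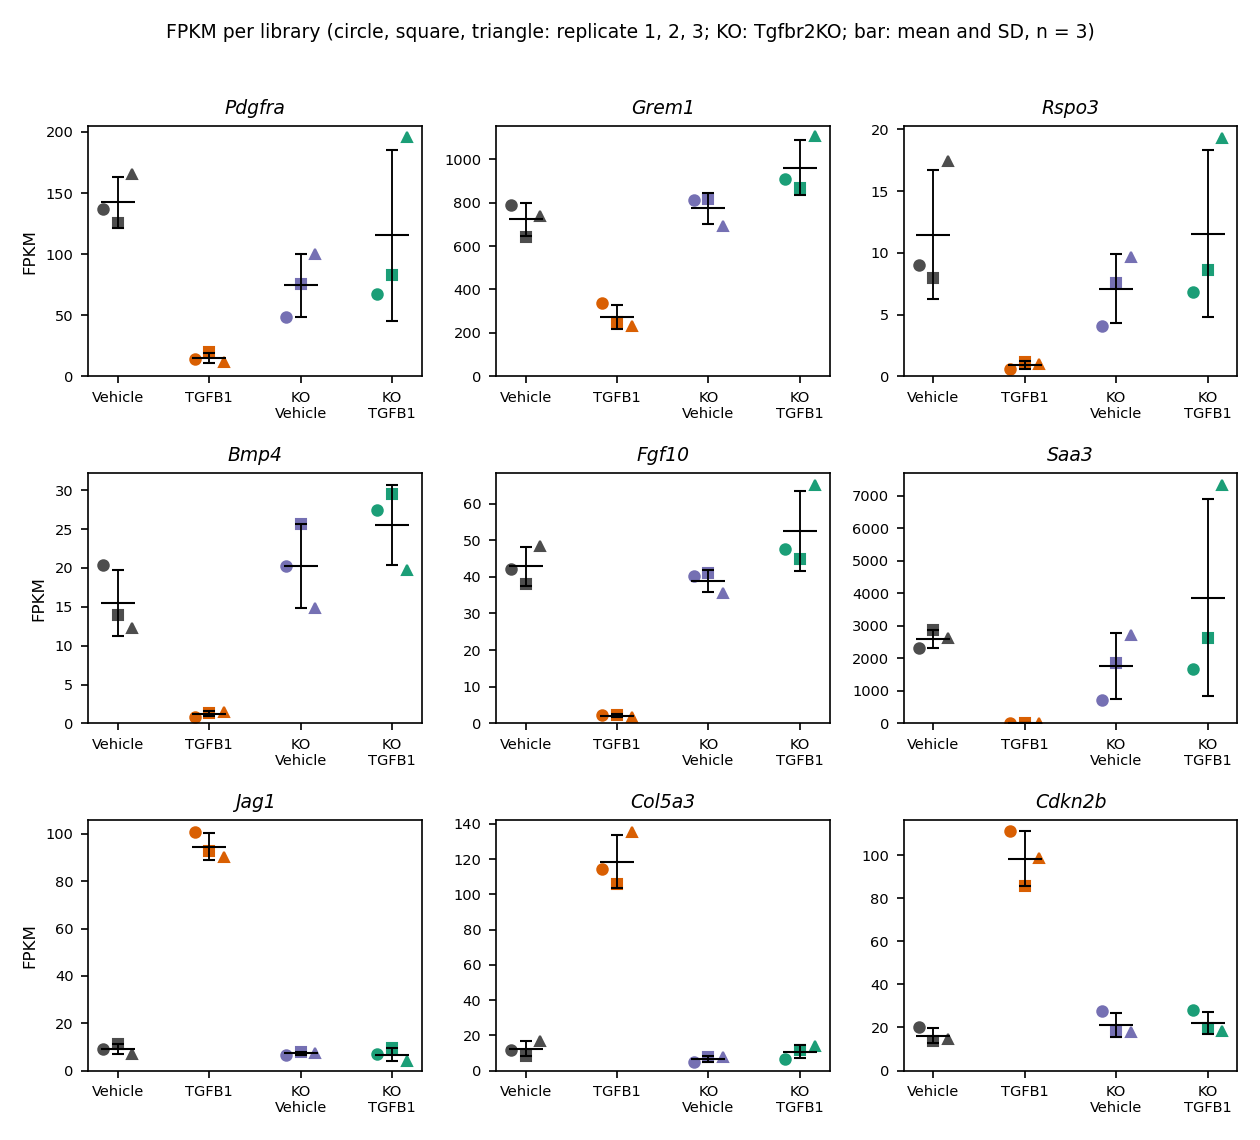
FPKM of 9 named genes in each of the 12 libraries, with the mean and SD of each group (n = 3) and the replicates as circles, squares and triangles. In TGFB1 libraries Pdgfra, Grem1, Rspo3, Bmp4, Fgf10 and Saa3 lie below, and Jag1, Col5a3 and Cdkn2b above, each library of the other 3 groups.

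Of 25 cell cycle genes 19 fell and none rose (21 adjusted over the list alone), each by a modest amount: cyclin genes Ccnb2 and Ccnb1 fell 2.22-fold and 2.12-fold, and the mitotic kinesin gene Kif20a 2.02-fold. The adipogenic and lipid storage list had 8 lower and 2 higher members of 15 (9 and 2 adjusted over the list alone), including the lipoprotein lipase gene Lpl (log2 -2.75), Fabp4 (-2.39) and Cebpd (-2.21). Cholesterol synthesis had 11 lower and 1 higher of 23 (12 and 3 adjusted over the list alone). The serine, proline and ATF4 list rose in 12 of 20 members with none lower (14 adjusted over the list alone), among them Psph (log2 0.81), Chac1 (0.81) and Asns (0.59). The camera adjusted p was 6.87e-09 for cell cycle, 0.000733 for adipogenic, 0.00254 for cholesterol and 0.000282 for serine, proline and ATF4. With an estimated correlation the adjusted p was 0.342, 0.0736, 0.585 and 0.342 in the same order. The 13 other tested lists had no call with the preset correlation. Among them, 7 of 20 genes rose and 5 fell for matrix proteases and inhibitors (9 and 5 adjusted over the list alone), 7 rose and 3 fell of 20 for MAPK immediate early and feedback, 7 rose and 3 fell of 19 for TGFB pathway components (7 and 4 adjusted over the list alone), 5 rose and 4 fell of 12 for WNT pathway targets and 5 rose and 2 fell of 9 for chondrogenic, osteogenic and tendon genes. For YAP-TEAD targets 4 rose and 2 fell of 14, for glycolysis and hypoxia 4 rose and 1 fell of 20, and for interferon response none rose and 1 fell of 19 (camera adjusted p = 0.0828, or 0.0482 with the replicate block). The tested cell type lists had 2 up and 2 down of 12 for fibroblast, 4 up and 2 down of 10 for smooth muscle and pericyte, 1 down of 7 for endothelial and 1 down of 12 for leukocyte (none adjusted over the list alone). Where no second pair of counts is given, the counts were the same adjusted over the list alone.

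Over all genes, 4033 of the 12641 changed with TGFB1 in cultures not labelled knockout (limma with trend, Benjamini-Hochberg adjusted p under 0.05), 2184 up and 1849 down. With upper-quartile scaling the balance turned, to 1750 up and 2105 down. At least 2-fold changes on the log2(FPKM + 1) scale were fewer among rising genes (264) than among falling genes (429).

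**Figure D3:**
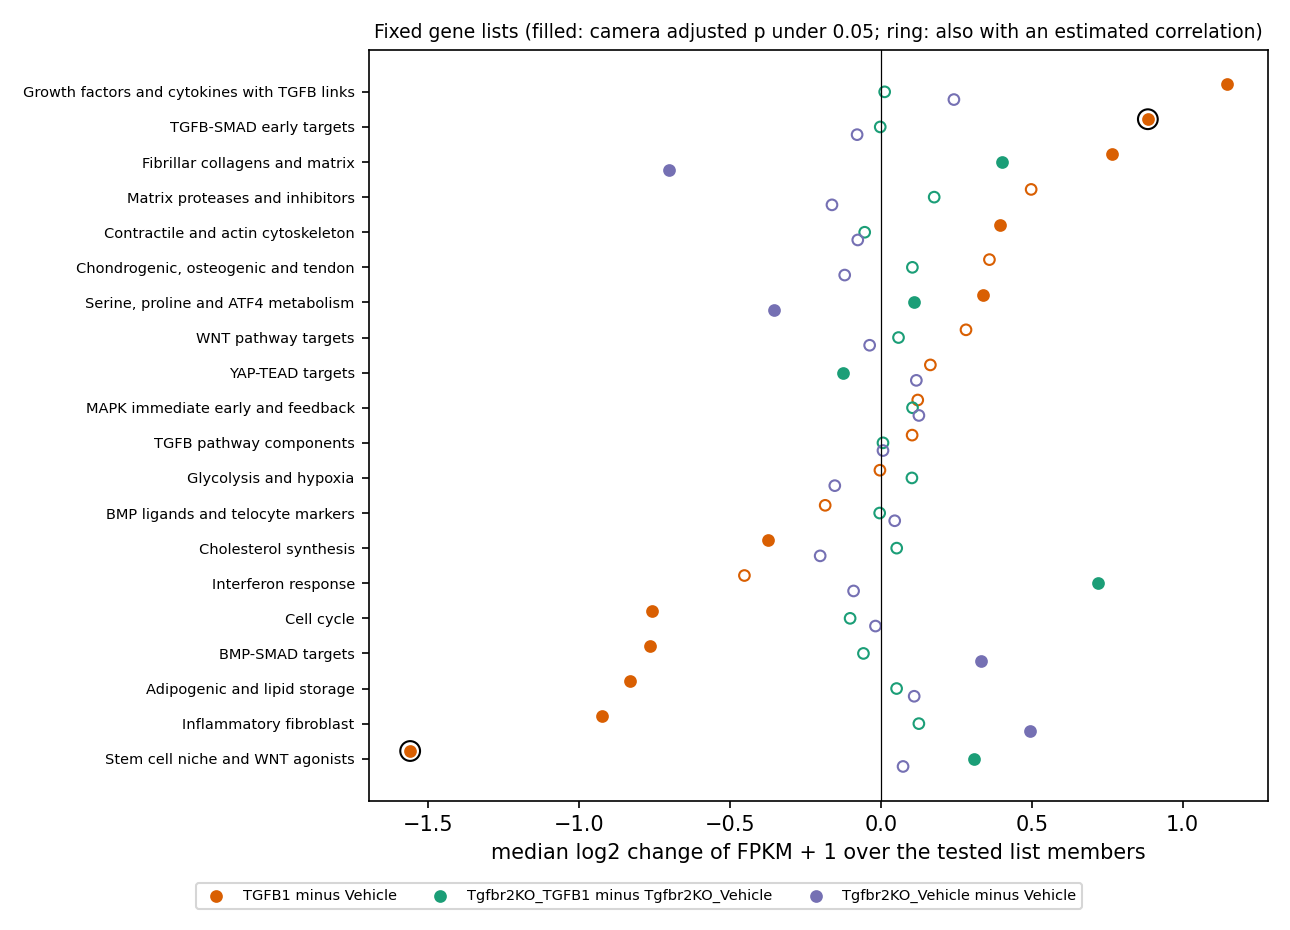
Median log2 change of FPKM + 1 over the tested members of the 20 fixed pathway lists, for TGFB1 minus Vehicle (orange), Tgfbr2KO_TGFB1 minus Tgfbr2KO_Vehicle (green) and Tgfbr2KO_Vehicle minus Vehicle (purple). Filled points passed camera with the preset correlation, and the 2 ringed points, early TGFB-SMAD targets at 0.88 and stem cell niche genes at -1.56, also passed with an estimated correlation.

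In Tgfbr2KO cultures no gene passed the threshold for TGFB1 (limma, 0 of 12641). An unadjusted p under 0.05 was reached by 748 genes, where 632 would be reached by chance, and the smallest adjusted p was 0.395. With the replicate number as a block the threshold was still passed by 0 genes, but 1897 had an unadjusted p under 0.05 (1976 with a block within each genotype) and the smallest adjusted p was 0.0717 (0.114 within genotype). The niche genes gave no call there: Grem1 had 774 ± 72.4 FPKM with vehicle and 962 ± 128 with TGFB1 (log2 0.31, SE 0.15, adjusted p = 0.738), and Rspo3 had 7.09 ± 2.80 and 11.6 ± 6.77 (SD, n = 3). Pdgfra was at 74.5 ± 25.8 FPKM with vehicle and 115 ± 69.9 with TGFB1 (log2 0.52, SE 0.38, adjusted p = 0.741). Bmp4 (log2 0.33), Il6 (0.47), Ccn2 (-0.25), Smad7 (-0.29), Tgfb1 (-0.06), Col1a1 (0.48) and Tgfbr2 (0.30) had adjusted p from 0.738 to 0.829, and Acta2 stood at 1778 ± 32.2 and 1802 ± 379.7 FPKM. Adjusted over the list alone, 3 of 20 MAPK immediate early and feedback genes were higher (camera adjusted p = 0.122). The TGFB-SMAD early targets had a median log2 change of 0.00 (camera adjusted p = 0.779, 1 up and 1 down adjusted over the list alone). Camera with the preset correlation called 5 lists: interferon response (median log2 0.72), matrix (0.40), stem cell niche (0.31) and serine, proline and ATF4 (0.11) upward and YAP-TEAD targets (-0.13) downward. None of the 5 passed with an estimated correlation (adjusted p = 0.620 for interferon response, matrix and niche, 0.673 for serine and 0.724 for YAP-TEAD). The serine, niche and YAP-TEAD calls were also lost when single libraries were left out: serine without Tgfbr2KO_Vehicle replicate 1 or Tgfbr2KO_TGFB1 replicate 3 (highest adjusted p = 0.0818), niche without replicate 3 of Tgfbr2KO_Vehicle or of Tgfbr2KO_TGFB1 (0.159), and YAP-TEAD without Tgfbr2KO_Vehicle replicate 1 or 2 or Tgfbr2KO_TGFB1 replicate 3 (0.533). Isg15 and Col3a1, of the interferon and matrix lists, rose unevenly over replicates 1, 2 and 3. Isg15 was at 4.33, 9.69 and 14.5 FPKM in Tgfbr2KO_Vehicle and 5.34, 40.9 and 86.4 FPKM in Tgfbr2KO_TGFB1. Col3a1 was at 126, 312 and 358 FPKM and at 242, 419 and 1304 FPKM in the same order. With the replicate block, cell cycle (adjusted p = 0.0446), glycolysis (0.0116) and fibroblast markers (0.0170) passed as well, where the fit without it gave 0.0584, 0.119 and 0.0584. In simulated data the same test on this comparison recovered 58.2% of genes changed by a log2 of 0.5, 82.1% at 1 and 100% at 2, and the 95% interval of the median gene reached 0.242 to either side. The simulated libraries were independent, with the same spread in all groups. The real Tgfbr2KO_TGFB1 libraries were the least alike (lowest r between replicates 0.957, against 0.969 to 0.982 in the other groups), so the real recovery may be lower. The count was 1476 with library weights, where 1 library, Tgfbr2KO_TGFB1 replicate 2, took a weight of 17.7 and the weights did not converge.

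The TGFB1 change differed between the genotypes for 2230 genes by the interaction term (limma adjusted p under 0.05), with 1059 higher and 1171 lower in the Tgfbr2KO response. With upper-quartile scaling these were 1186 and 1002. Of the 2230 genes, 2158 also changed with TGFB1 in cultures not labelled knockout. For Saa3 the log2 change with TGFB1 was -8.07 without the knockout label and 1.05 with it, a difference of 9.12 (SE 0.79, adjusted p = 9.73e-05). Differences were 6.80 for Lcn2, 5.93 for Cxcl5, 4.73 for Igfbp5 and 3.69 for Pdgfra (SE 0.53, adjusted p = 0.00149). Grem1 (1.72), Rspo3 (3.19), Bmp4 (3.19) and Il6 (2.66) differed in that direction too, with adjusted p from 0.000233 to 0.00423. The rises of Jag1 (-3.41), Tfpi2 (-3.32), Olfm2 (-3.08), Cdkn2b (-2.48), Nox4 (-1.56) and Tgfb1 (-0.91) were smaller in Tgfbr2KO cultures, with adjusted p from 9.22e-05 to 0.000789. Among lists, 10 of 15 niche genes were higher and 12 of 20 early TGFB-SMAD targets lower in the Tgfbr2KO response (10 up and 2 down, and 2 up and 15 down, adjusted over the list alone). Both lists passed camera with an estimated correlation (adjusted p = 0.0224 and 0.00895). Smad7 (-1.09, adjusted p = 0.102) did not pass, and did with the replicate number as a block (adjusted p = 0.00587). YAP-TEAD targets had an adjusted p of 0.0721, or 0.0339 with the block. The number of genes was 3658 with the replicate block and 1486 without TGFB1 replicate 1.

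**Figure D4:**
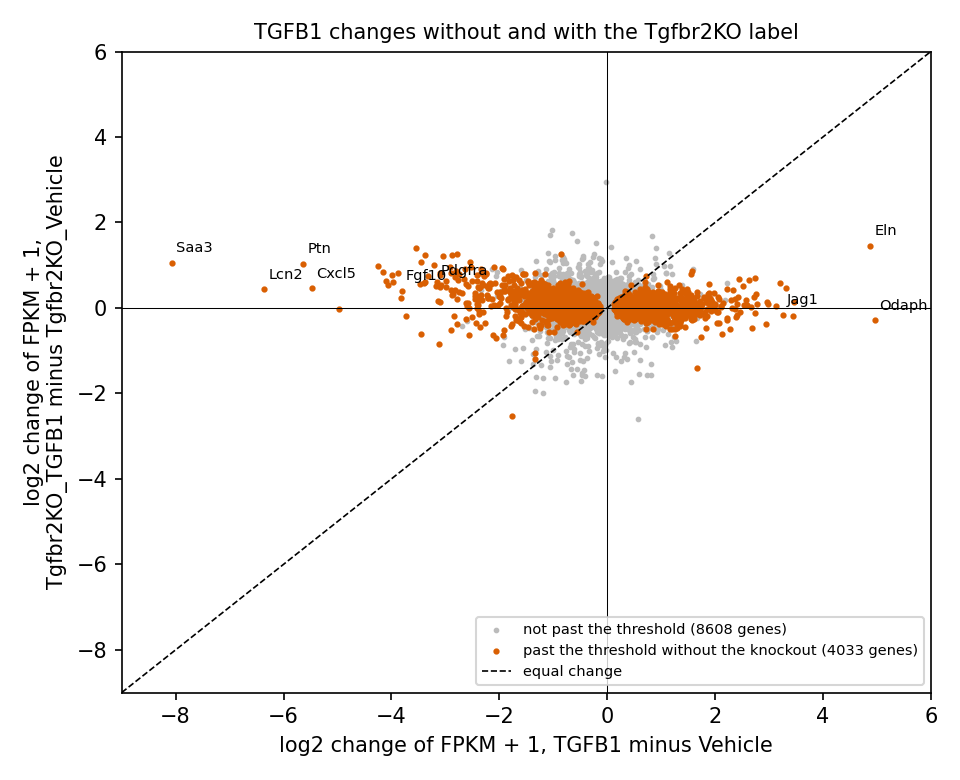
Log2 change with TGFB1 in cultures not labelled knockout (horizontal) against that in Tgfbr2KO cultures (vertical) for the 12641 tested genes, with the 4033 genes past the threshold without the knockout label in orange and the line of equal change dashed. The orange genes spread from -8.07 (Saa3) to 4.97 (Odaph) along the horizontal axis, and their median absolute change on the vertical one is 0.0921.

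Across genes, the change with TGFB1 in Tgfbr2KO cultures was nearly unrelated to that without the knockout label (Pearson r = -0.126 and Spearman rho = -0.072 over 12641 genes, which are not independent replicates). Over the 4033 changed genes r was -0.276 and rho -0.162, and the median absolute log2 change was 0.492 without and 0.0921 with the knockout label. The coefficient over all genes turned to 0.0359 without Tgfbr2KO_TGFB1 replicate 3.

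Without added TGFB1, Tgfbr2KO cultures differed from Vehicle cultures in 157 genes (limma adjusted p under 0.05), 66 higher and 91 lower. Mmp3, the gene of stromelysin 1, was at 3.11 ± 1.54 FPKM in Vehicle and 25.9 ± 14.0 in Tgfbr2KO_Vehicle (SD, n = 3; log2 2.62, SE 0.48, adjusted p = 0.0404), and the collagenase gene Mmp13 rose 9.03-fold. Crct1 rose to 33.7 ± 19.1 FPKM (log2 3.56, SE 0.51, adjusted p = 0.0258), and the cornified envelope genes Sprr1a and Ivl by log2 changes of 2.00 and 1.91. The protease inhibitor genes Slpi and Serpinb9b, Wdr92, Ifi209 and Lcn2 also rose, by 2.37, 1.64, 1.11, 1.69 and 1.16. Prl2c3 and Prl2c2 rose by 2.53 and 1.88, but these near-identical family members share reads and their split is uncertain. Krt8 was at 25.8 FPKM in Tgfbr2KO_Vehicle replicate 1 and at most 0.0542 FPKM in replicates 2 and 3.

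Among lower genes in Tgfbr2KO_Vehicle, Csrp2 fell 2.38-fold from 78.3 ± 12.3 FPKM (log2 -1.22, SE 0.16, limma adjusted p = 0.0249), Ccdc80 2.31-fold, Ltbp4, a latent TGF-beta binding protein gene, 2.22-fold, the protease gene Adamts12 2.19-fold and Ccn4 2.03-fold. Creb3l1 fell 2.00-fold and Cdh3 2.43-fold, and Rflnb, Carmn, Crispld2, Mir145a and Mtss2 fell by log2 changes from -0.87 to -0.75. Of the matrix list, Col6a3 passed over all genes (log2 -0.63) and 13 of 25 members were lower adjusted over the list alone (median log2 -0.70, camera adjusted p = 2.88e-06, but adjusted p = 0.350 with an estimated correlation). Of 20 serine, proline and ATF4 genes 4 fell, namely Slc7a5, Atf5, Aldh18a1 and Mthfd2 (16 down and 1 up adjusted over the list alone; median log2 -0.35, camera adjusted p = 1.22e-08, but adjusted p = 0.350 with an estimated correlation). Lcn2 and Vcam1 rose among 24 inflammatory genes, and Id1 and Id3 among 12 BMP-SMAD targets, and both lists were called upward beside S100a8, at 0.727 to 11.2 FPKM in Vehicle and 39.5 to 219 FPKM in Tgfbr2KO_Vehicle (4 and 2 up adjusted over the list alone; camera adjusted p = 0.000959 and 0.00508, but adjusted p = 0.350 for both with an estimated correlation). The fibroblast marker list was called downward with no member past the threshold over all genes (camera adjusted p = 0.0327, 1 up and 6 down adjusted over the list alone), but not with an estimated correlation (adjusted p = 0.689). BMP-SMAD targets lost the call without Tgfbr2KO_Vehicle replicate 1 (adjusted p = 0.0610), and fibroblast markers without that library or Vehicle replicate 3 (highest adjusted p = 0.0765), or with quantile normalization (0.0613). With the replicate block, cholesterol synthesis (0.0204), glycolysis (0.0192) and smooth muscle and pericyte markers (0.0192) passed as adjusted p, where the fit without it gave 0.0790, 0.141 and 0.109. Col1a1 was at 1189.7 ± 300.0 FPKM in Tgfbr2KO_Vehicle (log2 -1.26, SE 0.30, adjusted p = 0.0671, or 0.0121 with the replicate block). These other genes named beforehand did not pass: Pdgfra (-0.98), Smad7 (0.45), Rspo3 (-0.61), Il6 (0.55), Bmp4 (0.36), Tgfb1 (0.16), Grem1 (0.10), Acta2 (-0.07) and Ccn2 (0.06).

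In the vehicle comparison 2769 genes had an unadjusted p under 0.05, where 632 would be reached by chance. On leaving out single libraries, 1560 to 2819 genes did. The count of 157 past the adjusted threshold fell on leaving out any single library. It was 4 without Vehicle replicate 1, 86 without Vehicle replicate 2, 0 without Vehicle replicate 3, 0 without Tgfbr2KO_Vehicle replicate 1, 11 without Tgfbr2KO_Vehicle replicate 2 and 7 without Tgfbr2KO_Vehicle replicate 3, and it was 0 (2711 at an unadjusted p under 0.05) in a fit to the 6 compared libraries alone. With the replicate number as a block it was 1897, with 886 higher and 1011 lower, and these included each of the 157.

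Of the 157 genes that differed in vehicle, 67.5% moved the opposite way with TGFB1 in cultures not labelled knockout, where simulated unchanged groups sharing the Vehicle libraries gave 5.58%, or 3.22% where simulated libraries of 1 number also deviated together. Among genes called in both, 42 rose with TGFB1 and were lower in Tgfbr2KO_Vehicle, such as Csrp2 and Ccn4, and 30 fell with TGFB1 and were higher, such as Lcn2 and Slpi, while 11 rose and 12 fell in both. Independent lists of these sizes would overlap by 15.7, 9.65, 11.4 and 13.3 genes in that order, values that leave out the shared libraries. The 72 genes in opposite and 23 in the same direction compare with means of 0.53 and 107 in the simulation without shared numbers, and 0.2 and 117 in the one with them. Of the 4033 genes changed by TGFB1, 44.4% moved the opposite way in Tgfbr2KO_Vehicle, where the simulations gave 19.8% and 16.8%. TGFB1 changed no gene in the simulations, so their shares and overlaps are no baseline for genes that it did change. The covariance of the 2 sets of changes over all genes was 0.0188 (Pearson r = 0.099, Spearman rho = 0.117), against 0.0227 (r = 0.494) in the simulation without and 0.0174 (r = 0.550) in the one with shared numbers. The difference in covariance changed sign between these simulations (-0.00384 and 0.00144). With separate Vehicle libraries, 1 for one comparison and 2 for the other, a check chosen after seeing the data, the covariance ranged from -0.0303 to 0.0167 over the 6 divisions and was below 0 in 5.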

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

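The results here differed between the genotypes by the interaction test. Of the tests below, the splits of libraries were fixed beforehand, while those on the vehicle comparison and on the replicate numbers were chosen after the result was seen. Groups of 3 were not tested for a library far from the others.

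The response to TGFB1 differed between the genotypes for 2230 genes. Falls seen without the knockout label were smaller or absent in Tgfbr2KO cultures for Saa3 (difference in log2 change 9.12), Lcn2 (6.80), Ptn (6.67), Cxcl5 (5.93), Lgi2 (5.24), Spon2 (4.99), Hp (4.94), Ptx3 (4.94), Igfbp4 (4.74), Igfbp5 (4.73), Mgp (4.68), Ifitm1 (4.61), Pdgfra (3.69), Rspo3 (3.19), Bmp4 (3.19), Il6 (2.66) and Grem1 (1.72). Rises were smaller or absent for Odaph (-5.26), Eln (-3.42), Jag1 (-3.41), Tfpi2 (-3.32), Hbegf (-3.32), Acsbg1 (-3.16), Olfm2 (-3.08), Stmn4 (-2.88), Sema7a (-2.87), Mmp9 (-2.85), Ccn2 (-1.87) and Tgfb1 (-0.91). Mir8103 also differed (-3.18), with log2 changes of 0.58 without and -2.60 with the knockout label, neither past the threshold. The call was lost for Ptn without TGFB1 replicate 1 (adjusted p = 0.0552). It was lost for Mmp9 without replicate 2 or 3 of TGFB1 or Tgfbr2KO_Vehicle (highest adjusted p = 0.0577), and for Eln without any of those 4 or Vehicle replicate 1 or 2 (0.0589), and for Eln also with a pseudocount of 0.1 (0.141) or 0.5 (0.0551). For Ccn2 it was lost without Vehicle replicate 3, any TGFB1 replicate, or Tgfbr2KO_Vehicle replicate 1 or 2 (0.0638). For Mir8103 it was lost without any of 9 libraries, namely those other than Vehicle replicate 2, TGFB1 replicate 2 and Tgfbr2KO_TGFB1 replicate 1 (0.0746), without a filter (0.0537) or with a replicate block within each genotype (0.0650).

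Lists that differed upward in the Tgfbr2KO response were stem cell niche genes (median difference 2.10), interferon response (1.21), inflammatory fibroblast (1.20), adipogenic (0.83), cell cycle (0.64), BMP-SMAD targets (0.54) and cholesterol synthesis (0.42). Growth factors (-1.22), early TGFB-SMAD targets (-1.02), matrix (-0.63), contractile genes (-0.40) and serine, proline and ATF4 genes (-0.29) differed downward. With an estimated correlation 10 of these 12 lists lost the call, with adjusted p of 0.566 for interferon response, cell cycle, cholesterol, matrix, contractile and serine genes, 0.141 for BMP-SMAD targets, 0.0838 for growth factors and 0.0659 for inflammatory and adipogenic genes. The matrix and serine lists also lost it without Vehicle replicate 2 or Tgfbr2KO_TGFB1 replicate 1 (highest adjusted p = 0.0663), and with quantile normalization (0.272 for matrix and 0.392 for serine).

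Other groupings of the same libraries were tried. For TGFB1 in cultures not labelled knockout 1 of 10 splits, the real one, gave as many genes as 4033, and the highest other gave 1. For the vehicle comparison it was also 1 of 10, with 157 genes against 2, and in Tgfbr2KO cultures 10 of 10 reached the real count of 0, with 1 gene as the highest other. With 3 libraries against 3 there are too few splits for a share under 0.05. For the interaction 5 of 100 drawn reassignments of the 200 possible gave at least 2230 genes, the highest other 3567. By the rule set beforehand this share did not exclude chance, but it cannot decide on it. Of the 100, 15 kept the 3 TGFB1 libraries together, the real one included, and with them the difference between the treated groups. The 4 others that reached 2230 all exchanged the genotype of the 3 treated libraries as a whole. The 85 that mixed treated libraries gave at most 1 gene.

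The first pattern weighed was that 34 genes separated the replicate numbers in all 4 groups. A chance order of the numbers was excluded, since 1 of 100 drawn orders, the real one, separated as many and the highest other separated 4. Whether a strain or donor variant moved reads between near-identical copies stayed open: the share of the first copy separated the numbers in 4 of 4 pairs, but the pairs were picked after their values were seen. For Atp6v0c against its pseudogene that share was 99.1% to 100% in number 1, 43.9% to 47.8% in number 2 and 0.382% to 1.26% in number 3. A batch that goes with the number stayed open. Outside those pairs lay 28 separated genes, but this count cannot tell a batch from a donor, since a difference between donors could separate such genes too. The labels give no batch apart from the number.

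The second pattern weighed was the difference between Tgfbr2KO_Vehicle and Vehicle. Across genes it correlated with differences between numbers within Tgfbr2KO_TGFB1, at an r of 0.565 for 1 minus 3, 0.536 for 2 minus 3 and 0.241 for 1 minus 2, but weakly within TGFB1 (0.138, 0.0195 and 0.112), so variation between cultures could contribute. RNA from epithelial cells that express the keratins Krt8, Krt5 or Krt14 was excluded as the whole cause. In numbers 2 and 3 these keratins were at most 0.0646 FPKM, while Crct1 was at least 19.3 FPKM there and at most 2.53 FPKM in Vehicle. In number 1 such RNA could contribute. Epithelial cells without these keratins were not tested for. Krt18 was at most 0.522 FPKM in numbers 2 and 3, and Krt19, present in every group, was 6.94 and 9.30 FPKM there against 5.34 to 8.15 FPKM in Vehicle. Loss of signalling through Tgfbr2 without added ligand may also contribute, as 67.5% of the genes moved the opposite way with TGFB1. The simulated 5.58% and 3.22% are no baseline for this share, because TGFB1 changed no gene in the simulations. Of the 4033 genes changed by TGFB1, however, 44.4% moved the opposite way in Tgfbr2KO_Vehicle. The 20 early TGFB-SMAD targets had a median log2 change of -0.08 there, with none past the threshold over all genes. Adjusted over the list alone 6 were lower and 1 higher, and camera did not call the list (adjusted p = 0.118). This explanation thus stayed open.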

How the results depend on the processing

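The 4033 genes changed by TGFB1 without the knockout label stayed within 1.5 times that count under every processing alternative and on leaving out any single library. Without all libraries of a number, chosen after seeing the data, the count ranged from 1394 (number 2) to 3715 (number 3). In Tgfbr2KO cultures the count of 0 became 1 with a pseudocount of 0.1 (Mir212, chosen after its values were seen, 0 FPKM in all 3 Tgfbr2KO_Vehicle libraries) and 1476 with library weights. It stayed 0 with the replicate block and on every omission. The interaction count of 2230 became 3658 with the replicate block, 3558 with a replicate block within each genotype and 4784 with library weights, and ranged on omissions from 295 (without number 2) to 2457 (without Tgfbr2KO_TGFB1 replicate 1). The vehicle count of 157 became 1897 with the replicate block, 71 without a filter, where more genes were tested, 90 without the variance trend, 2509 with library weights and 0 in a fit to the compared libraries alone, and ranged on omissions from 0 (without Vehicle replicate 3, among others) to 86 (without Vehicle replicate 2). The library weights did not converge and gave Tgfbr2KO_TGFB1 replicate 2 a weight of 17.7. Of 33 list calls 4 remained with an estimated correlation. The correlation of TGFB1 changes between genotypes ranged from -0.180 (without Vehicle replicate 2) to 0.0359 (without Tgfbr2KO_TGFB1 replicate 3), a reversal. The contractile list in Tgfbr2KO cultures reversed from a median of -0.05 to 0.088 without Tgfbr2KO_TGFB1 replicate 3, and was -0.14 without Tgfbr2KO_TGFB1 replicate 1. For the changes with no reason given, the cause was not tested. Among the results reported, and apart from the calls given with the block in the text, the replicate block changed no other call and moved no other count of calls by over 1.5 times. The share of 44.4% that moved the opposite way in vehicle stayed under 50% with a pseudocount of 0.1, a filter at 5 FPKM or quantile normalization, and was 39.2% to 48.3% on leaving out single libraries (jackknife SE 8.13, so 50% lies within 1 SE). Relative depth ranged from 0.744 to 1.24, and without absolute depth the limit it sets for low genes was not known.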

Other observations

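Immediate early genes were weighed as a last pattern, in Tgfbr2KO cultures with TGFB1, and the tests apart from the stress genes were chosen after the result was seen. Fos and Egr1, chosen after their values were seen, had log2 changes of 1.27 (SE 0.27) and 1.14 (SE 0.25), higher in 3 of 3 pairs, and both missed the threshold (larger adjusted p = 0.643), so a response that does not need Tgfbr2 may exist but was not established. By the interaction their changes differed from those without the knockout label (adjusted p = 0.00453 for Fos and 0.0321 for Egr1), but Fos itself fell with TGFB1 there (log2 -0.86, adjusted p = 0.0332). The list of 20 immediate early and feedback genes had a median log2 change of 0.11, above 99.63% of random lists, with 11 members higher and 6 lower in 3 of 3 pairs (21.9% and 19.5% of all tested genes were). Camera did not call it (adjusted p = 0.122), except without Tgfbr2KO_Vehicle replicate 1 (0.0330) or Tgfbr2KO_TGFB1 replicate 3 (0.00383), so chance stayed open. Handling at harvest could not be excluded either. The 14 stress genes had a median log2 change of 0.0847 and were split. Higher in 3 of 3 pairs were 4, namely Nr4a1 (log2 0.94), Zfp36 (0.36), Nfkbiz (0.32) and Atf3 (0.32), none past the threshold. Hsph1 (-0.26), Gadd45b (-0.18) and Maff (-0.24) were higher in none.

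S100a8 was at 0 to 0.967 FPKM in TGFB1 and 10.3 to 188 FPKM in Tgfbr2KO_TGFB1. Lyz2 was at 107, 304 and 241 FPKM in Tgfbr2KO_Vehicle replicates 1, 2 and 3 and at 87.0, 226 and 156 FPKM in Tgfbr2KO_TGFB1, so it was lower with TGFB1 in all 3 pairs of both genotypes.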
